A study of Danio rerio with 6 samples.

How the data were processed

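Cardiomyocytes of the atrioventricular canal were profiled in 6 libraries, 3 GFP-positive and 3 GFP-negative, sorted from adult zebrafish carrying a β-catenin reporter. Per the labels' protocols, the canal region was cut from hearts of fish aged 4 to 8 months and digested with collagenase at 3 mg/ml for 30 min. Cells were stained with the dead-cell dye SYTOX blue and sorted by fluorescence, and RNA was purified with a NucleoSpin XS kit. cDNA was made with SMART-Seq v4 and libraries with an NEBNext Ultra II Directional kit, per the labels' protocols. SMART-Seq v4 amplifies cDNA before the library is made and adds no molecular identifiers, so counts include amplification copies, and counting intervals and floors cover counting error only.

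The authors deposited 1 table per library of whole-number total counts per gene, not normalized, per the file headers and the values, with a zebrafish gene symbol and an Ensembl gene identifier in each of 25281 rows. The identifiers were the same in all 6 tables. The aligner, the counting program and its rules for shared, overlapping or antisense reads, the genome build and the annotation version are not given in the sources used here, so no coordinates are printed. Genes with close copies, such as the haemoglobins, keratins, gstm genes, cardiac actins and the neighbouring ventricular myosin genes myh7 and myh7l, and genes that overlap others, are uncertain to the degree that the authors' counting could split or share their reads. Counts summed to 14783352 to 19750914 per library.

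Groups and replicate numbers were taken from the sample titles. The sorted-fraction label of the GFP-negative libraries and the labels' protocol both name an mCherry-negative, EGFP-positive sort for them, which conflicts with their titles and descriptions. Each library was counted as a separate sample, as the titles number them. The chi-square per degree of freedom of pairs within a group, 32.1 to 102, shows only that no library's counts were present under 2 titles; it treats amplification copies as independent and does not show that the samples were separate.

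Differences between genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: genes were kept by filterByExpr, libraries scaled by TMM, dispersions estimated with group as the only term, and the quasi-likelihood F test applied with robust fitting. p-values were adjusted by Benjamini-Hochberg over 13490 genes, with 0.05 as the threshold. Fold changes are GFP-positive over GFP-negative, each with a standard error taken from the fold change and its F value, and levels are TMM-scaled CPM, counts per 1e6 counts of a library, given as mean ± SD over 3 libraries. A gene with 1 to 3 counts in a group has a ratio with an exact 95% counting interval, and a gene with 0 counts a bound against 3 counts over the group. Library shares were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3.

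The 28 gene lists, 17 of pathways and gene classes, 10 of cell type markers and 1 of dissociation stress, were written from textbook knowledge. Of their 767 entries, 734 matched a row by symbol or by the gene name table. The 27 lists with at least 5 tested members were tested with limma 3.58.1 by camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. With an estimated correlation, camera also takes its degrees of freedom from the few libraries, so its p can be larger without a larger correlation. Members past the threshold were also counted when adjusted over the list alone.

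The design, the lists and the rule for named genes were chosen before the data were examined. The rule named the 8 largest fold changes in each direction among called genes with a mean of at least 10 CPM, separated groups and a proper symbol; 19 fixed genes whatever their values; up to 4 called members of each list with the smallest adjusted p, or the 2 smallest where none was called; and the 2 most abundant members of each cell type list. The values of 1 gene that the rule named are not reported here. The fixed gene vmhc matched no row by its symbol; whether the gene named myh7 in the files (ENSDARG00000079564) is the same gene was not settled, and its values are given as myh7 only. mt-co1 and the genes of the closing paragraphs on symbol families were chosen after their values were seen.

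The fit was tested on simulated counts for these 13490 genes, with 200 changed by known factors. The 200 were drawn from genes with a mean above 5 CPM, so the recovery below does not cover genes of lower level. With 1 spread for both groups, it recovered 12%, 50%, 74% and 96% of genes changed 2-fold, 4-fold, 8-fold and 16-fold, and called 6 of 13290 unchanged genes. With each group's own spread, it recovered 2%, 26%, 70% and 90% and called 0 unchanged genes. The list test found the 1 shifted list and called 0 of 26 others. Its genes were simulated as independent, with 1 spread for both groups, so this does not test false calls in lists of correlated genes. At these spreads, a change of 2-fold was seldom detectable.

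Alternatives covered DESeq2 1.42.0 size factors, upper-quartile and no composition factors, no expression filter and a stricter one (at least 10 counts in at least 3 libraries and a mean of at least 5 CPM), the DESeq2 Wald test, limma-voom with and without sample quality weights, a fit with replicate number as a block, removal of mitochondrially encoded and haemoglobin genes, a minimum fold of 2, and each library left out in turn. Added after the data were seen were a fit with each library's smooth trend on abundance removed (loess span 0.5), list tests under further settings, and member counts without each library. Corrections for GC content and gene length were not run.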

Results

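The transcriptome of cardiomyocytes from the atrioventricular canal of the adult zebrafish heart was measured by RNA-seq in 6 sorted-cell libraries. The atrioventricular canal is the ring of tissue between atrium and ventricle that carries the valves and delays conduction. The fish carried a reporter in which the DNA-binding domain of the yeast activator GAL4 is joined to a shortened TCF and made from the myl7 promoter, which is active in cardiomyocytes. EGFP driven by GAL4 target sequences then marks cardiomyocytes in which β-catenin activates transcription, and mCherry made from the same promoter marks cardiomyocytes as such. The GFP-positive group, named β-catenin ON in the labels, and the GFP-negative group, named β-catenin OFF, had 3 libraries each. Total counts were 16275969, 17210180 and 19750914 in GFP-negative replicates 1, 2 and 3, and 14783352, 15934231 and 15583204 in GFP-positive replicates 1, 2 and 3.

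Groups were taken from the sample titles. A further label of the GFP-negative libraries and the protocol both name an mCherry-negative, EGFP-positive sort for them, which conflicts with those titles, so the sort gate of that group is not settled. The cardiomyocyte myosin light chain gene myl7 (ENSDARG00000019096) stood at 28794 ± 5232 CPM (TMM-scaled counts per 1e6 counts of a library; SD, n = 3) in the GFP-negative and 14594 ± 1704 CPM in the GFP-positive libraries. The labels do not say whether replicates came from separate fish or sorts, so p-values measure only the spread between these samples, which may be technical.

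The libraries of the groups differed in composition as well as in single genes. Transcripts encoded in the mitochondrial genome took 11.9% to 15.7% of the counts in the 3 GFP-negative and 35.6% to 44.9% in the 3 GFP-positive libraries. The means were 14.1 ± 2.01% and 40.3 ± 4.65% (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allows). Of 13 mitochondrially encoded genes tested, 12 rose in GFP-positive libraries, among them mt-co1 (log2 fold change 1.73 ± 0.19 SE, adjusted p = 0.00833, edgeR). The log2 fold changes of all 13 lay between 1.39 and 1.86. Haemoglobin transcripts took 0.302 ± 0.0706% of GFP-positive and 0.0993 ± 0.0138% of GFP-negative counts. Of the tested genes, a mean of 984 ± 274 had no count in a GFP-positive library and 27.7 ± 33.5 in a GFP-negative library.

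GFP-positive libraries were less alike than GFP-negative libraries. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.956 to 0.973 between GFP-negative and 0.706 to 0.761 between GFP-positive libraries. The biological coefficient of variation was 0.266 within the GFP-negative and 1.04 within the GFP-positive group. GFP-positive replicate 3 had the fewest genes with at least 10 counts, 10093 against 12031 and 12834 in GFP-positive replicates 1 and 2, and stood apart from the other 5 libraries on the first principal component, which held 48.5% of the variance.

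**Figure D1:**
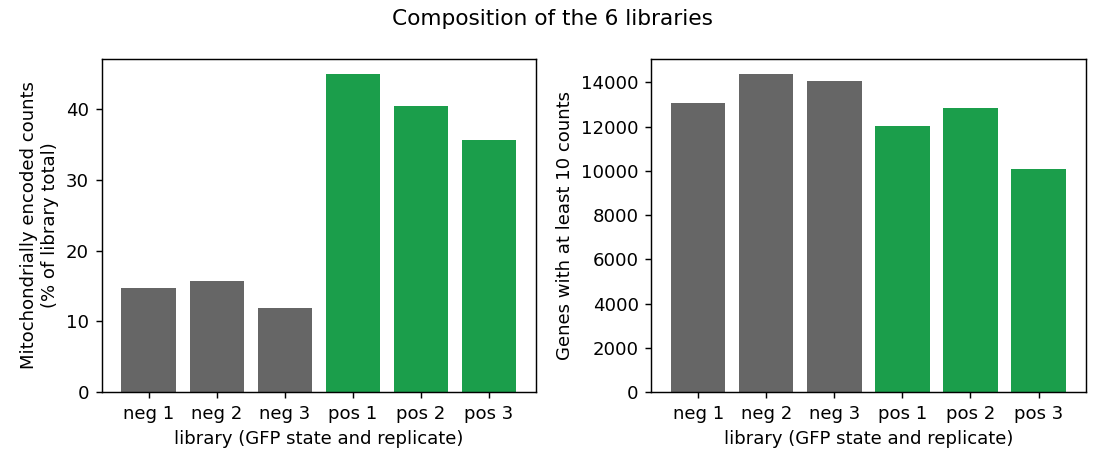
Share of counts from mitochondrially encoded genes (left, percent of the library total) and number of genes with at least 10 counts (right) in each of the 3 GFP-negative (grey) and 3 GFP-positive (green) libraries; each bar is 1 library. Mitochondrially encoded shares lie between 35.6% and 44.9% in GFP-positive and between 11.9% and 15.7% in GFP-negative libraries.

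The comparison of GFP-positive with GFP-negative cardiomyocytes asks how transcription differs between canal cardiomyocytes with and without active Wnt/β-catenin signalling. In the GFP-positive libraries wif1 (ENSDARG00000005541), a secreted Wnt inhibitor, was 21.1-fold higher, tbx2b (ENSDARG00000006120), a T-box repressor of the atrioventricular canal, 3.27-fold higher, and the atrial myosin gene myh6 (ENSDARG00000090637) 3.66-fold higher. The ventricular myosin genes myh7 (ENSDARG00000079564) and myh7l (ENSDARG00000079782) were 8.01-fold and 7.93-fold lower. Nuclear genes of oxidative phosphorylation, fatty acid oxidation and glycolysis were lower, with 31 of 63, 9 of 25 and 9 of 30 tested members past the threshold. Markers of endocardium, fibroblasts, epicardium and erythrocytes were higher in the same libraries by limma camera with a preset correlation. With an estimated correlation, adjusted p = 0.347, 0.214 and 0.374 for the metabolic lists in that order and 0.188, 0.214, 0.188 and 0.188 for the marker lists. None of the 7 list calls held in that version, which also has fewer degrees of freedom than the preset one. Among 13490 genes tested, 280 rose and 288 fell at an edgeR adjusted p under 0.05.

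The split between directions depended on the scaling. It was 258 higher and 450 lower with upper-quartile factors, which moved the median log2 fold change of all genes to -0.11. It was 196 and 507 without a composition factor (median -0.16), and 329 and 213 with each library's trend on abundance removed, an alternative added after the data were seen (median 0.21). With TMM factors the median was 0.01, and log2 fold changes below are on that scale. All 568 called genes had non-overlapping groups, as did 3999 of all tested genes (29.6%, where chance gives 10% for 3 against 3). The count of 568 was 51, 147 and 44 without GFP-negative replicates 1, 2 and 3, and 223, 131 and 1018 without GFP-positive replicates 1, 2 and 3.

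By size of change, the leading higher genes with a mean of at least 10 CPM were atp1a1b, snap25a, tnni1d, myoz1a, wif1, col10a1b, mllt11 and gyg1b. atp1a1b (ENSDARG00000019856), an alpha subunit of the sodium pump, rose from 1.59 ± 0.780 to 40.2 ± 7.99 CPM (SD, n = 3; log2 fold change 4.65 ± 0.45 SE, adjusted p = 0.00620). snap25a (ENSDARG00000020609), a membrane fusion protein gene known from nerve endings, had a log2 fold change of 4.55 ± 0.41 (adjusted p = 0.00526). The muscle genes tnni1d, a troponin I, and myoz1a, a Z-disc protein, had log2 fold changes of 4.45 ± 0.43 and 4.43 ± 0.41 (adjusted p = 0.00526 for both). col10a1b, a collagen X gene, stood at 4.28 ± 0.65, mllt11 at 3.91 ± 0.66 and the glycogenin gene gyg1b at 3.84 ± 0.63 (adjusted p = 0.0195, 0.0264 and 0.0249). The naming rule required non-overlapping groups, so by selection all 8 genes were higher in each GFP-positive library than in any GFP-negative one.

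The leading lower genes were nhsl1a, tnni4a, slc9a6a, mpped2, hrh3, efcab11, gfod2 and myh7. tnni4a (ENSDARG00000099870), a troponin I gene, fell from 1223 ± 107 to 99.3 ± 15.7 CPM (log2 fold change -3.62 ± 0.19, adjusted p = 9.21e-04). myh7 fell 8.01-fold, from 1918 ± 454 to 239 ± 42.4 CPM (SE of the log2 fold change 0.24, adjusted p = 0.00427). mpped2, a metallophosphoesterase gene, fell from 266 ± 18.9 to 25.6 ± 2.92 CPM (-3.38 ± 0.18, adjusted p = 9.21e-04), and nhsl1a had a log2 fold change of -3.94 ± 0.44 (adjusted p = 0.00869). The sodium/proton exchanger gene slc9a6a, the histamine receptor gene hrh3, efcab11 and gfod2 had log2 fold changes of -3.40 ± 0.63, -3.28 ± 0.71, -3.06 ± 0.50 and -3.02 ± 0.58, with adjusted p from 0.0255 to 0.0489. The calls of efcab11, gfod2, hrh3, gyg1b and mllt11 were each lost in 5 of the 6 fits that left out 1 library, and kept without GFP-positive replicate 3.

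Targets and feedback genes of Wnt/β-catenin signalling were higher as a group. Of 12 tested members, 4 rose and 8 did not pass the test; adjusted over the list alone, 7 rose and 0 fell. All 12 had positive fold changes, with a median of 1.67 (limma camera adjusted p = 7.22e-07, and 0.144 with an estimated correlation). The estimated correlation, -0.00288, was below the preset 0.01, so a larger correlation does not account for the larger p. That version of the test also has fewer degrees of freedom. wif1 rose from 10.8 ± 2.94 to 228 ± 38.2 CPM (log2 fold change 4.40 ± 0.28, adjusted p = 0.00223). notum1b, a secreted enzyme gene that inactivates Wnt ligands, rose by 2.59 ± 0.30, apcdd1l by 2.08 ± 0.43 and the cyclin D1 gene ccnd1 by 1.88 ± 0.29 (adjusted p = 0.00920, 0.0457 and 0.0191). axin2 (ENSDARG00000100149), a feedback inhibitor that is transcribed in response to β-catenin, stood at 10.2 ± 2.05 CPM in GFP-negative and 28.1 ± 5.78 CPM in GFP-positive libraries, with no overlap, and did not pass the threshold (1.46 ± 0.33, adjusted p = 0.0513, 0.00101 to 0.233 over the alternatives). lef1, sp5a and nkd1 had fold changes of 1.17 ± 1.03, 0.82 ± 1.04 and 2.97 ± 0.98 that did not pass the test (adjusted p = 0.685, 0.811 and 0.150). Members that rose numbered 1, 2 and 1 without GFP-negative replicates 1, 2 and 3. The mitochondrially encoded share, 40.3% against 14.1%, separated the same libraries.

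Among 37 tested Wnt ligands, receptors and pathway components, 2 rose and 35 did not pass; adjusted over the list alone, 3 rose and 1 fell. The ligand gene wnt4 rose from 2.36 ± 0.619 to 28.5 ± 4.00 CPM (log2 fold change 3.59 ± 0.39, adjusted p = 0.00822). frzb, a secreted frizzled-related Wnt antagonist, rose from 34.7 ± 12.9 to 393 ± 140 CPM (3.50 ± 0.41, adjusted p = 0.00891). The list median was 0.51 (camera adjusted p = 0.00739; adjusted p = 0.188 with an estimated correlation). The list call was lost under the stricter expression filter (adjusted p = 0.246) and without GFP-positive replicate 1 (0.0623). Endocardium, fibroblast and epicardium markers (medians 1.75, 1.70 and 2.26) and the mitochondrially encoded share (40.3% against 14.1%) were also higher in the GFP-positive libraries. Without GFP-positive replicate 3, the library that stood apart, 6 members rose and 1 fell; without GFP-negative replicates 1 and 3, 1 and 0 rose.

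**Figure D2:**
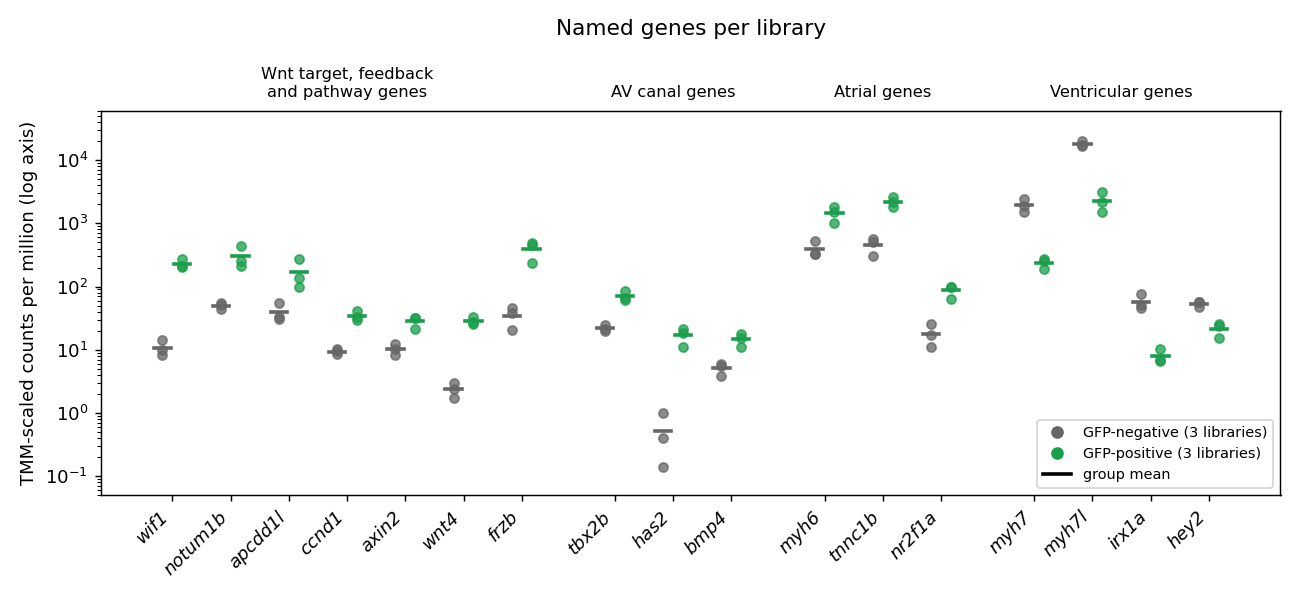
TMM-scaled CPM (log axis) of genes from 5 lists in each GFP-negative (grey) and GFP-positive (green) library; each point is 1 library and each horizontal line a group mean (n = 3). wif1 lies at 8.41 to 14.1 CPM in GFP-negative and 201 to 272 CPM in GFP-positive libraries, and myh7l at 16768 to 19791 and 1525 to 3136 CPM.

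Genes of atrioventricular canal myocardium were higher as a group: 2 of 13 tested members rose and 11 did not pass, and adjusted over the list alone 4 rose and 1 fell. tbx2b rose by 1.71 ± 0.23 on the log2 scale, to 71.7 ± 12.9 CPM (adjusted p = 0.0124). has2, the hyaluronan synthase gene of the endocardial cushions, rose from 29 counts over the GFP-negative to 734 over the GFP-positive libraries (5.03 ± 0.83, adjusted p = 0.0259). The ligand gene bmp4 stood at 5.13 ± 1.14 and 14.9 ± 3.40 CPM without passing the test (1.53 ± 0.45, adjusted p = 0.104). tbx3a, a T-box gene of the canal and conduction system, had 108 counts over the GFP-negative libraries and 3 over the GFP-positive ones, a ratio of 27.8 (95% counting interval 9.26 to 137), and did not pass the test (adjusted p = 0.128). The list median was 1.53 (camera adjusted p = 0.00873; adjusted p = 0.214 with an estimated correlation). Camera no longer passed without GFP-negative replicate 1 (adjusted p = 0.0848), without GFP-positive replicate 1 (0.184) and without an expression filter (0.0740). Members that rose numbered 0 without GFP-negative replicate 1 or 3, and 1 without GFP-negative replicate 2 or GFP-positive replicate 1 or 2. has2 is also known from endocardium, whose markers had a median of 1.75.

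Pacemaker and conduction genes did not pass the test for a shift in 1 direction. None of 14 tested members passed the edgeR test (1 rose adjusted over the list alone; 5 at an unadjusted p under 0.05; 3 with DESeq2 and 1 with limma-voom), and the median was 0.38 (camera adjusted p = 0.294; adjusted p = 0.475 with an estimated correlation). fry's test for changes in either direction passed (adjusted p = 2.61e-05). It also passed for every other list tested except the macrophage, lymphocyte and thrombocyte markers, so this is not particular to conduction genes. Of these genes, 1 rose without GFP-positive replicate 2 and 1 fell without GFP-positive replicate 3. kcne4, a potassium channel subunit gene, came nearest with 2.08 ± 0.46 (adjusted p = 0.0516). hcn4, the pacemaker channel gene, had 48 counts over the GFP-negative and 2 over the GFP-positive libraries, too few for the expression filter, a ratio of 18.5 (95% counting interval 4.86 to 157). The interval covers counting error only, and hcn4 was not tested. A mean of 984 tested genes had no count in a GFP-positive library, against 27.7 in a GFP-negative one. isl1 had 0 and 2 counts, so no fold is given. tbx18, shox2 and the T-type calcium channel gene cacna1g had log2 fold changes of 0.99 ± 1.31, 0.28 ± 1.55 and -1.18 ± 0.42, none past the test (adjusted p = 0.824, 0.971 and 0.179).

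Of 9 tested genes of ventricular working myocardium, 4 fell and 5 did not pass, and adjusted over the list alone 5 fell. The median was -1.45 (camera adjusted p = 2.89e-04, and 0.188 with an estimated correlation of 0.00996, near the preset 0.01). myh7l fell from 17986 ± 1594 to 2269 ± 812 CPM (-2.99 ± 0.28, adjusted p = 0.00526). The homeobox gene irx1a fell by 2.85 ± 0.33 on the log2 scale and hey2, a Notch-related repressor gene of ventricular cells, by 1.33 ± 0.27 (adjusted p = 0.00891 and 0.0416). The sodium channel gene scn5lab and the gap junction gene cx43 had fold changes of -1.40 ± 0.81 and 1.07 ± 0.71 that did not pass (adjusted p = 0.452 and 0.535). The mitochondrially encoded share, 40.3% against 14.1%, and endocardium, fibroblast and epicardium markers, with medians of 1.75, 1.70 and 2.26, were higher in the same libraries. Members that fell numbered 2 without GFP-negative replicate 1 or 3, and the list call was lost without GFP-positive replicate 1 (adjusted p = 0.0666).

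Of 11 tested genes of atrial working myocardium, 5 rose and 6 did not pass; adjusted over the list alone, 6 rose and 1 fell (median 1.87, camera adjusted p = 0.00371; adjusted p = 0.188 with an estimated correlation). myh6 rose from 392 ± 109 to 1435 ± 407 CPM (1.87 ± 0.28, adjusted p = 0.0192) and the troponin C gene tnnc1b from 457 ± 133 to 2213 ± 384 CPM (2.28 ± 0.26, adjusted p = 0.00891). The transcription factor gene nr2f1a rose by 2.29 ± 0.36 (adjusted p = 0.0210). The atrial natriuretic peptide gene nppa stood at 3874 ± 543 and 3318 ± 417 CPM and did not pass (-0.22 ± 0.17, adjusted p = 0.601). The list call was lost without GFP-positive replicate 1 (adjusted p = 0.0666) and without GFP-positive replicate 3 (0.109). Members that rose numbered 1, 2 and 1 without GFP-negative replicates 1, 2 and 3, and 2 and 3 without GFP-positive replicates 1 and 2; 1 member fell without GFP-positive replicate 1. Endocardium, fibroblast and epicardium markers (medians 1.75, 1.70 and 2.26) and the mitochondrially encoded share (40.3% against 14.1%) were higher in these libraries too.

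Sarcomere and Z-disc genes were lower on balance, with exceptions. In the same libraries the mitochondrially encoded share (40.3% against 14.1%) and endocardium, fibroblast and epicardium markers (medians 1.75, 1.70 and 2.26) were higher. Of 33 tested members, 10 fell, 2 rose and 21 did not pass; adjusted over the list alone, 13 fell and 3 rose. The Z-disc actinin gene actn2b fell 2.29-fold (SE of the log2 fold change 0.18), the M-band gene myom1b by 1.40 ± 0.23 on the log2 scale and myl7 by 0.98 ± 0.18 (adjusted p = 0.0195, 0.0239 and 0.0321). tcap, the titin-capping protein gene, rose from 458 ± 119 to 2053 ± 233 CPM (2.16 ± 0.22, adjusted p = 0.00702), and myh6 was the other member that rose. The median was -0.57 (camera adjusted p = 0.0266; adjusted p = 0.625 with an estimated correlation). Camera no longer passed without GFP-negative replicates 1 and 3 (adjusted p = 0.0848 and 0.0680), without GFP-positive replicates 1 and 2 (0.0888 and 0.472) and with the abundance trend removed (0.0744), the replicate block gave 0.0517 and fry 0.0724, and the 10 members that fell were 0 to 4 when 1 library was left out.

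Calcium handling genes showed no call: none of 20 tested members passed the edgeR test, over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05; 2 with DESeq2 and 1 with limma-voom; median -0.28, camera adjusted p = 0.490; adjusted p = 0.625 with an estimated correlation). casq2, which encodes the calcium store protein calsequestrin, had -0.58 ± 0.15 (adjusted p = 0.0770), ryr2b, a calcium release channel gene, -0.53 ± 0.35 (0.526), and fkbp1ab 1.79 ± 0.69 (0.210). fry's test for changes in either direction did pass for the calcium handling list (adjusted p = 0.00389), as it did for most lists. Without GFP-positive replicate 3, 1 calcium handling gene rose and 2 fell. Among 10 sodium and potassium channel genes, kcnq1.1 rose (1.34 ± 0.25, adjusted p = 0.0343; 4 rose and 1 fell adjusted over the list alone), and among 8 connexin genes cx36.7 rose (1.55 ± 0.29, adjusted p = 0.0321; 1 rose and 2 fell adjusted over the list alone). Both calls were lost without a composition factor and without GFP-negative replicate 1, 2 or 3 or GFP-positive replicate 1, and that of cx36.7 also without GFP-positive replicate 2. Without GFP-positive replicate 2, 2 sodium and potassium channel genes rose, and without GFP-positive replicate 3, 1 rose and 3 fell. Neither list passed camera (adjusted p = 0.338 and 0.153; adjusted p = 0.675 and 0.401 with an estimated correlation). Of 32 cardiac transcription factor genes, tbx2b and nr2f1a rose, hey2 fell and 29 did not pass (2 and 2 adjusted over the list alone). Their median was -0.03, positive with DESeq2 size factors or the abundance trend removed, and camera gave adjusted p = 0.407 (adjusted p = 0.580 with an estimated correlation), while fry passed as lower (adjusted p = 0.0322). Without GFP-positive replicate 3, 2 of these genes rose and 5 fell; without GFP-positive replicate 1 or 2, 1 rose and 0 fell, and without GFP-negative replicate 1, 2 or 3 none passed.

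BMP, TGF-beta and Notch pathway genes were higher on balance: 4 of 29 tested members rose, 1 fell and 24 did not pass, and adjusted over the list alone 8 rose and 2 fell. smad6b, an inhibitory SMAD induced by BMP signalling, rose from 27.7 ± 1.58 to 99.3 ± 10.6 CPM (1.84 ± 0.19, adjusted p = 0.00702). The BMP-responsive genes id1 and id4 rose 4.59-fold and 2.83-fold (SE of the log2 fold change 0.23 and 0.32, adjusted p = 0.00702 and 0.0457), and hey2 was the member that fell. Endocardium and fibroblast markers, with medians of 1.75 and 1.70, and the mitochondrially encoded share, 40.3% against 14.1%, were higher in the same libraries. The list median was 1.13 (camera adjusted p = 0.00881, and 0.188 with an estimated correlation of -0.0261, below the preset 0.01). Camera no longer passed without GFP-positive replicate 1 or 3 (adjusted p = 0.0666 and 0.0735) and without an expression filter (0.135). Members that rose numbered 1, 2 and 0 without GFP-negative replicates 1, 2 and 3 and 2 without GFP-positive replicate 1 or 2.

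Nuclear genes of oxidative phosphorylation were lower almost throughout. Of 63 tested members, 31 fell and 32 did not pass, and adjusted over the list alone 60 fell and 0 rose. ndufa4 fell from 769 ± 126 to 204 ± 21.0 CPM (-1.92 ± 0.18, adjusted p = 0.00526), and the ATP synthase gene atp5fa1 and the cytochrome c oxidase genes cox6b1 and cox7a1 fell by 1.27 ± 0.15, 1.29 ± 0.16 and 1.24 ± 0.16 (adjusted p = 0.00989, 0.00989 and 0.0123). The median was -0.85 (camera adjusted p = 1.69e-12; adjusted p = 0.347 with an estimated correlation). The mitochondrially encoded subunits of the same complexes moved the other way, with a median of 1.57. Members that fell numbered 2, 13 and 1 without GFP-negative replicates 1, 2 and 3, and 2, 1 and 21 without GFP-positive replicates 1, 2 and 3.

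Fatty acid oxidation and glycolysis genes were lower as well, in libraries with a higher mitochondrially encoded share (40.3% against 14.1%). Endocardium, fibroblast and epicardium markers, with medians of 1.75, 1.70 and 2.26, were higher there too. So were atrial genes (median 1.87), while ventricular genes were lower (median -1.45). Of 25 fatty acid oxidation genes, 9 fell and 16 did not pass (22 fell adjusted over the list alone; median -1.06, camera adjusted p = 5.02e-08; adjusted p = 0.214 with an estimated correlation). fabp3, the heart fatty acid binding protein gene, fell from 2191 ± 601 to 289 ± 67.5 CPM (-2.92 ± 0.26, adjusted p = 0.00526). acadvl, the very-long-chain acyl-CoA dehydrogenase gene, and ppargc1a, a co-activator gene of mitochondrial biogenesis, fell by 1.97 ± 0.22 and 2.02 ± 0.28 (adjusted p = 0.00869 and 0.0158). Of 30 glycolysis genes, 9 fell, 1 rose and 20 did not pass; adjusted over the list alone 16 fell and 1 rose (median -0.90, camera adjusted p = 3.49e-05; adjusted p = 0.374 with an estimated correlation). aldoaa fell from 8528 ± 1993 to 2063 ± 590 CPM (-2.05 ± 0.26, adjusted p = 0.0119), eno3 by 1.92 ± 0.27, tpi1b by 1.47 ± 0.25 and hk1 by 0.97 ± 0.17. Without GFP-negative replicates 1, 2 and 3, 2, 4 and 2 fatty acid oxidation genes and 1, 3 and 0 glycolysis genes fell. Without GFP-positive replicates 1 and 2, the numbers were 3 and 2 for fatty acid oxidation and 1 and 0 for glycolysis.

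Cell cycle genes were higher by the list test, with 1 of 34 tested members past the test for single genes. aurkb, a mitotic kinase gene, rose from 3.93 ± 1.24 to 16.9 ± 1.62 CPM (4.29-fold, SE of the log2 fold change 0.45, adjusted p = 0.0463), and adjusted over the list alone 0 members rose or fell (6 at an unadjusted p under 0.05; 4 with DESeq2 and 1 with limma-voom). Endocardium, fibroblast and erythrocyte markers, with medians of 1.75, 1.70 and 1.69, and the mitochondrially encoded share, 40.3% against 14.1%, were higher in the same libraries. The median was 0.98 (camera adjusted p = 0.00364; adjusted p = 0.295 with an estimated correlation). The list call was lost with limma's fry (adjusted p = 0.196) and without GFP-positive replicate 1 (0.0744), and that of aurkb with upper-quartile or no composition factors, without an expression filter, with the replicate block and without each of 5 libraries, all but GFP-positive replicate 3.

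Natriuretic and stretch-related genes were mixed: 4 of 13 tested members rose, 1 fell and 8 did not pass, and adjusted over the list alone 6 rose and 2 fell. ccn2a, a matricellular growth factor gene, rose from 36.3 ± 1.59 to 138 ± 19.1 CPM (1.92 ± 0.19, adjusted p = 0.00526), and the smooth muscle genes acta2 and tagln rose by 1.68 ± 0.28 and 3.50 ± 0.61 (adjusted p = 0.0260 and 0.0280). The skeletal actin gene acta1b fell 2.82-fold (SE of the log2 fold change 0.28, adjusted p = 0.0346). Members that rose numbered 1 without GFP-negative replicate 1, 2 or 3 and 2 without GFP-positive replicate 1 or 2, and 1 fell without GFP-negative replicate 2 but 0 without any other library. The median of 0.12 turned to -0.04 without a composition factor and to -0.03 without the filter, and the camera call (adjusted p = 0.0304) gave adjusted p = 0.374 with an estimated correlation. The list call was also lost under either other filter (adjusted p = 0.226 and 0.229), with mitochondrially encoded and haemoglobin genes removed (0.0673), and without GFP-negative replicate 2 (0.295) or GFP-positive replicate 1, 2 or 3 (0.180, 0.0502 and 0.146).

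Markers of cell types that a cardiomyocyte gate would exclude were also measured. Of 20 endocardium or endothelium markers, 4 rose and 0 fell (12 rose adjusted over the list alone; median 1.75, camera adjusted p = 8.93e-09; adjusted p = 0.188 with an estimated correlation). egfl7 rose from 23.0 ± 3.17 to 86.9 ± 20.3 CPM (1.92 ± 0.25, adjusted p = 0.0123), and aqp1a.1, sox7 and clec14a by 2.40 ± 0.40, 2.63 ± 0.44 and 1.97 ± 0.40. The von Willebrand factor gene vwf had 1.56 ± 0.43 without passing (adjusted p = 0.0884). Of 20 fibroblast or valve interstitial markers, 4 rose (11 adjusted over the list alone; median 1.70, camera adjusted p = 4.29e-08; adjusted p = 0.214 with an estimated correlation), among which the collagen gene col1a1b had the smallest adjusted p, from 68.7 ± 28.1 to 297 ± 35.1 CPM (2.11 ± 0.32, adjusted p = 0.0195), with postnb, dcn and fn1b at 2.75 ± 0.46, 2.04 ± 0.37 and 2.02 ± 0.38. Of 13 epicardium markers, 8 rose (9 adjusted over the list alone; median 2.26, camera adjusted p = 1.26e-08; adjusted p = 0.188 with an estimated correlation), among them gstm.3, krt94, krt15 and krt4 at 2.53 ± 0.21, 2.37 ± 0.26, 2.44 ± 0.30 and 2.47 ± 0.36. In each GFP-negative library, 18, 16 and 11 of the 3 lists' tested members also reached at least 1 CPM. Without GFP-negative replicate 1 or 3, 0, 0 and 2 members of the 3 lists rose; without GFP-negative replicate 2, 1, 2 and 3; without GFP-positive replicate 1, 3, 2 and 5; without GFP-positive replicate 2, 1, 0 and 4; and without GFP-positive replicate 3, 7, 5 and 8.

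Markers of blood cells were tested list by list, and differences between these lists were not tested. Of 16 erythrocyte markers, 6 rose (10 adjusted over the list alone; median 1.69, camera adjusted p = 4.04e-08; adjusted p = 0.188 with an estimated correlation). The number that rose was 4 without GFP-negative replicate 2 or GFP-positive replicate 1 or 2, and 1 and 2 without GFP-negative replicates 1 and 3; without GFP-positive replicate 3, 6 rose and 1 fell. The haemoglobin genes hbba1_2, hbaa1, hbba1_1 and hbba2 rose by 1.73 ± 0.15, 1.71 ± 0.18, 1.66 ± 0.19 and 2.00 ± 0.23 (adjusted p from 0.00459 to 0.00891). None of 20 macrophage markers passed edgeR, over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom); their median was -0.08, and 0.05 with the abundance trend removed (mean 0.12; camera adjusted p = 0.780; adjusted p = 0.931 with an estimated correlation). The most abundant, grn1 and cd74a, had 0.27 ± 1.19 and 0.08 ± 0.65. Of 13 neutrophil markers, lyz fell, with 79 counts over the GFP-negative and 0 over the GFP-positive libraries (at least 20.3-fold lower against a floor of 3 counts over the group; adjusted p = 0.0496, 1 fell adjusted over the list alone); its call was lost in 10 of 16 alternatives: with DESeq2 size factors, without an expression filter, with the replicate block, with mitochondrially encoded and haemoglobin genes removed, with the abundance trend removed, and without each library but GFP-positive replicate 3. srgn and cpa5 had 1.16 ± 0.40 and 0.54 ± 0.18 and did not pass (adjusted p = 0.168 and 0.141). The neutrophil median of 0.54 and mean of -0.22 differed in sign (camera adjusted p = 0.812; adjusted p = 0.931 with an estimated correlation).

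Of the remaining cell type lists, 2 of 10 smooth muscle or mural markers rose, acta2 and tagln (2 adjusted over the list alone), while rgs5b had 0.05 ± 0.23; 0 rose without GFP-negative replicate 1, 2 or 3 or GFP-positive replicate 1 in turn, and 1 without GFP-positive replicate 2; camera gave adjusted p = 0.334 (adjusted p = 0.625 with an estimated correlation). Of 10 thrombocyte markers, fn1b, which the fibroblast list also holds, rose, but in none of the fits without 1 library other than GFP-positive replicate 3 (1 adjusted over the list alone; camera adjusted p = 0.0988, adjusted p = 0.496 with an estimated correlation), and the list passed without GFP-positive replicate 3 (adjusted p = 0.0417) and with the abundance trend removed (0.0351). None of 6 lymphocyte markers passed edgeR (0 adjusted over the list alone, at an unadjusted p under 0.05, with DESeq2 or with limma-voom; camera adjusted p = 0.780, adjusted p = 0.878 with an estimated correlation); gata3 and ikzf1 had 2.72 ± 1.19 and 0.04 ± 1.90. The 4 neuron or glia markers tested were too few for the list test; snap25a rose (2 rose adjusted over the list alone), and syt1a stood at 23.7 ± 9.84 and 12.9 ± 1.87 CPM.

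Genes of dissociation stress and the immediate early response were higher by the list test: 4 of 37 tested members rose, 1 fell and 32 did not pass, and adjusted over the list alone 8 rose and 2 fell (median 0.27, camera adjusted p = 0.00881; adjusted p = 0.267 with an estimated correlation). ccn1, egr3 and atf3 rose by 1.37 ± 0.17, 2.22 ± 0.32 and 0.96 ± 0.19 (adjusted p = 0.0112, 0.0163 and 0.0396), and the orphan receptor gene nr4a1 fell by 0.76 ± 0.16 (adjusted p = 0.0425). Members that rose numbered 0, 1 and 0 without GFP-negative replicates 1, 2 and 3 and 2, 1 and 3 without GFP-positive replicates 1, 2 and 3, and 0 fell in any of these 6 fits. The mitochondrially encoded share was 40.3% against 14.1% in the same libraries. Of the 27 lists tested, 17 passed camera, 12 higher and 5 lower, 16 passed fry and 0 passed with an estimated correlation (6 at an unadjusted p under 0.05).

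**Figure D3:**
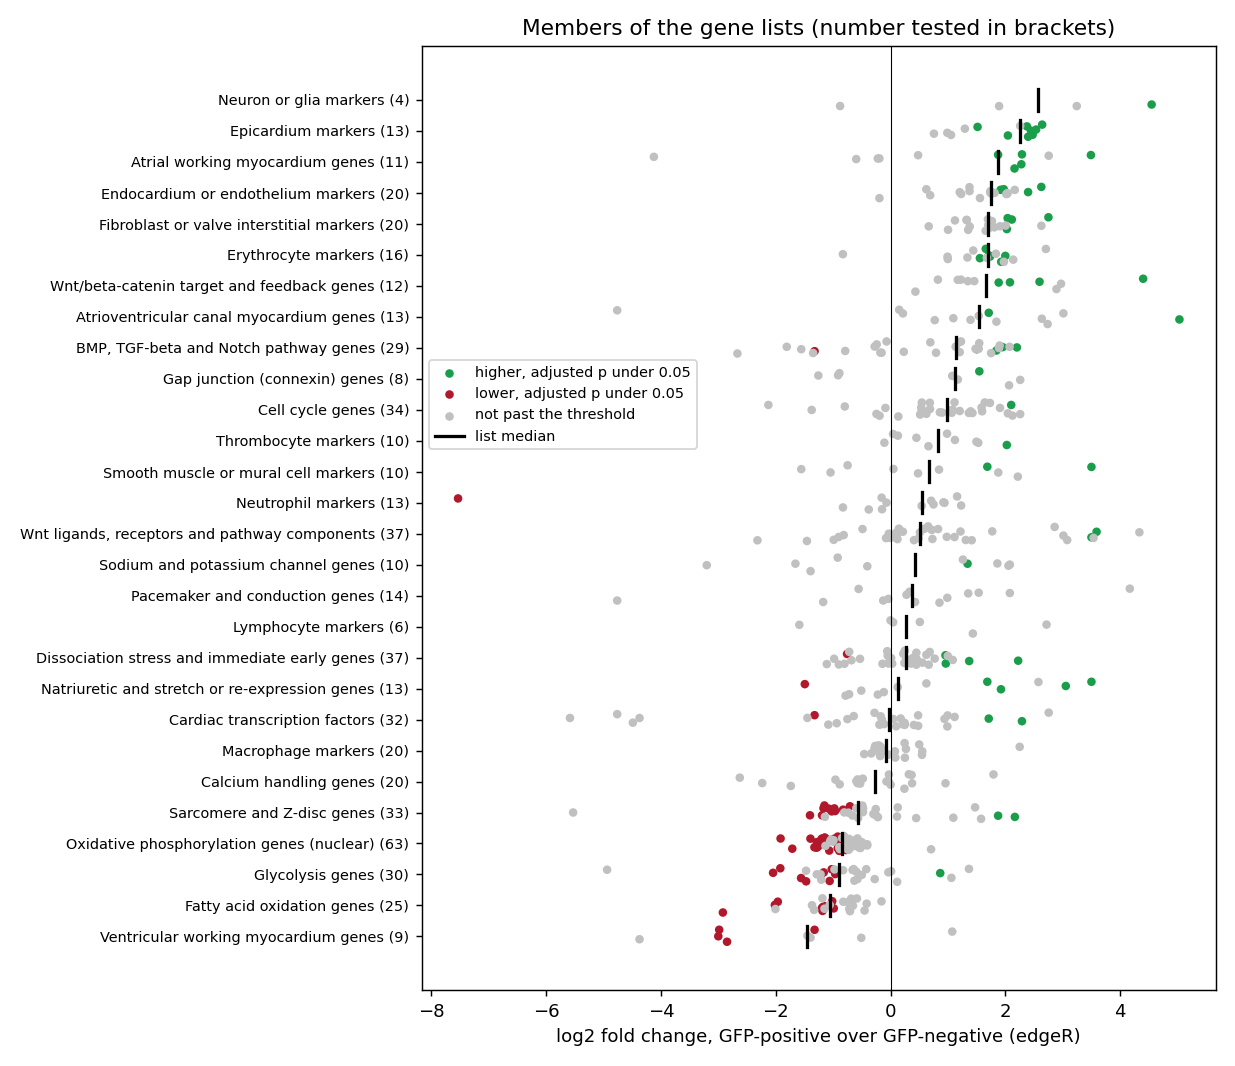
log2 fold change (GFP-positive over GFP-negative, edgeR) of each tested member of the 28 gene lists; each point is 1 gene, coloured where the adjusted p is under 0.05, each bar is the list median, and the neutrophil gene lyz, with 0 counts in GFP-positive libraries, is drawn at its fitted value, which is no bound. Medians run from -1.45 for ventricular genes to 2.26 for epicardium markers among the lists of at least 5 members; those of the cardiac transcription factor, macrophage, natriuretic and lymphocyte lists change sign with the scaling or filter.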

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

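The fits with the abundance trend removed, and the list tests under upper-quartile or no composition factors, without a filter and with mitochondrially encoded and haemoglobin genes removed, were chosen only after the results were seen; the others were planned. None of the 77 called results for named genes and none of the 17 called lists reversed in the alternatives run for them; the other called genes were not followed one by one. The count of 568 genes (280 higher, 288 lower) lay between 481 and 726 under the other scalings, filters, the fold minimum, quality weights, the replicate block, the trend removal and the removal of mitochondrially encoded and haemoglobin genes. It was 1667 with the DESeq2 Wald test (938 higher, 729 lower; 568 shared) and 860 with limma-voom (311 and 549; 533 shared); the cause was not tested. Leaving out 1 library gave 44 to 1018 genes, with fewer samples in each fit. It fell below 568 without each of 5 libraries and rose to 1018 (497 shared) without GFP-positive replicate 3, the library least like the others. Of 77 called results for named genes, 16 were kept in all alternatives: acadvl, atp1a1b, ccn2a, fabp3, gstm.3, hbba1_2, krt94, mpped2, myh7, myh7l, myoz1a, ndufa4, snap25a, tnni1d, tnni4a and wif1. Of the 61 others, 38 were lost only when a library was left out, and 13 of 29 uncalled genes, axin2 and kcne4 among them, passed in at least 1 alternative. Of 27 lists, 17 passed camera and 0 passed with an estimated correlation. Leaving out 1 library gave 9 to 16 lists, with 9 without GFP-positive replicate 1.

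The replicate numbers are shared between the groups, but the labels do not say that they pair samples. Deviations from the group means correlated across genes at 0.131, 0.187 and 0.0922 between samples of the same number and at -0.0123 or lower between others, so each sample correlated best with its own number, a hint from the data and not the design, but not every pair passed 0.1. Taking deviations from group means forces positive and negative values to balance for each sample. The negative values are therefore no separate support for pairing. The fit with the replicate block called 572 genes (436 shared) and 16 lists, without the sarcomere list (adjusted p = 0.0517). A block with a GC and length offset, and that offset alone, were not run, since no sequence was used here. Depth limits genes of low abundance: 3 counts correspond to 0.152 to 0.203 CPM in 1 library.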

Other observations

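The symbol families, the tests on marker mixtures and the comparison of marker lists with macrophage markers were chosen only after the results were seen. So were the contrast of metabolic with sarcomere genes and the test on starting molecules. The tests on splits, abundance trends, mitochondrial scaling and thinning were set before. The list test that the mitochondrial scaling test also used is among those added after the results were seen. Among 143 families of at least 10 genes that share a symbol stem, 14 passed camera and 0 passed with an estimated correlation (smallest adjusted p = 0.853; 3 at an unadjusted p under 0.05). Genes of the mitochondrial ribosome were lower in GFP-positive cardiomyocytes: the 47 mrpl genes, of the large subunit, had a median log2 fold change of -0.84 with 6 members that fell, and the 29 mrps genes, of the small subunit, -0.85 with 5 that fell. mrps27 fell by 1.84 ± 0.32 and mrpl23 by 1.16 ± 0.20 (edgeR adjusted p = 0.0262 for both). The 12 coq genes of coenzyme Q synthesis had a median of -0.82, with coq3, coq8aa and coq9 past the test, and the 10 tomm genes of the outer-membrane import machinery -0.71 with none. In the other direction, the 24 collagen genes had a median of 1.34, of which col10a1b and col1a1b rose, and the 11 annexin genes 0.71. anxa2a and anxa1a rose by 2.59 ± 0.24 and 2.38 ± 0.33 (adjusted p = 0.00526 and 0.0154). These directions held under the 4 other scalings.

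The real split of the 6 libraries gave 568 genes and 17 lists. Of the 10 ways to split them 3 against 3, 1 gave as many genes and 1 as many lists, the real one in both cases. The highest other split gave 0 genes by edgeR (75 to 280 at an unadjusted p under 0.05 over the other splits) and 13 lists. With 10 splits, no share under 0.05 can be reached. Each other split mixes GFP-positive with GFP-negative libraries, so the group difference widens the spread within each side and lowers its calls. The 0 genes are therefore no measure of what unrelated libraries would give. The split with 13 lists set GFP-negative replicates 1 and 3 with GFP-positive replicate 3 against the others.

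Markers of endocardium, fibroblasts and epicardium were higher in GFP-positive libraries, although the mCherry-positive gate that the labels name for these libraries would remove those cells. A trend of fold change with abundance is argued against: their median of 1.76 lay at percentile 100 of random lists matched on abundance, whose central range was -0.19 to 0.32. Cells or free RNA carried along in a fixed mix may account for the endocardium and fibroblast markers, with egfl7 at 86.9 CPM and col1a1b at 297 CPM. Their fold changes scattered by no more than their errors (heterogeneity per degree of freedom 0.960 and 0.621). Low scatter does not speak for a mix, since members were treated as independent while their estimated correlations were 0.238 and 0.340. Macrophage markers, which had no call, scattered less still (0.477). The epicardium markers scattered more (2.92), but this cannot decide against 1 mix. A marker's fold change from a mix also depends on any other source of its counts. In each GFP-negative library, 11 of the 13 epicardium markers reached at least 1 CPM. A lower share of cardiomyocytes raising all other cell types alike cannot be told apart, since the difference between these markers and macrophage markers was 2.03 (2 SE bounds 0.25 to 3.82, exact permutation p = 0.2) and libraries of the groups overlapped. Expression of these genes in the β-catenin-active cardiomyocytes themselves stays open and untested.

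Nuclear genes of energy metabolism were lower while mitochondrially encoded RNA was higher. The larger mitochondrially encoded share scaling other genes down is argued against, since with TMM factors the median of all tested genes was 0.01. The oxidative phosphorylation median was still -0.83 with those genes removed before scaling. TMM trims extreme genes, so this removal could change little and adds little to the argument. A trend with abundance is argued against too: the median of the 3 metabolic lists, -0.87, lay at percentile 0 of matched lists (central range -0.26 to 0.04). A loss of cytoplasmic RNA that lowers all nuclear-encoded cardiomyocyte transcripts strictly alike is argued against. The difference between metabolic and sarcomere or calcium handling genes was -0.45 (2 SE bounds -0.70 to -0.19, exact permutation p = 0.1, the smallest possible). The sarcomere list holds tcap and myh6, which rose by 2.16 and 1.87 and lift its mean. Medians depend little on single genes and differed in the same direction. They were -0.85, -1.06 and -0.90 for oxidative phosphorylation, fatty acid oxidation and glycolysis, against -0.57 for sarcomere and -0.28 for calcium handling genes. An unequal loss is not covered by this contrast. Of the 33 tested sarcomere genes, 10 fell and 2 rose. Among those that fell, myl7 and myom1b, at -0.98 and -1.40, lay below the oxidative phosphorylation median of -0.85. Atrial genes, with a median of 1.87, were higher and ventricular genes, with a median of -1.45, lower in the same libraries. The metabolic shift was not tested apart from these. A change of energy metabolism with β-catenin activity may also lower these nuclear metabolic genes and stays open. Cells damaged to different degrees in the sort, with unequal loss of transcripts, may do so too and stay open.

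GFP-positive libraries were less alike than GFP-negative ones. Fewer reads from nuclear genes are argued against: with each library thinned to 8148380 such counts, mean correlations within the groups were 0.960 and 0.738, a gap of 0.223. Fewer starting molecules cannot be told apart, because the ratio of the groups' coefficients of variation was 3.47 among the 3373 least abundant genes but still 1.79 among the 3373 most abundant ones, between the bounds set for either outcome. The number of sorted cells per library is not given in the sources used here, and a more varied population of GFP-positive cardiomyocytes was not tested.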
